A study of Mus musculus with 3 samples.

How the data were processed

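The values are those of 3 Affymetrix arrays hybridised with biotin-labelled material from total RNA from CD4+ CD8+ mouse thymocytes, 1 array per littermate cohort. Per the labels' protocols, thymuses were strained and cells were sorted by CD8 and then CD4 beads, and RNA was extracted with TRIzol. The same protocol text describes formaldehyde fixation before the sort, and it does not say whether the RNA samples were fixed. The submitters' processing notes name the R package affy, with no version. The background correction, normalization and summarization settings and the array's genome build are not given in the sources used here. The deposited values are log2 expression values, 1 per probe set and array, rounded to 2 decimals. That unit was read from the values, which run from 1.6 to 14.94. The sorted values of any 2 arrays differ by at most 0.15 and those of arrays 1 and 2 typically by 0.02, so the deposited values of the arrays share nearly the same distribution. A global difference in RNA content between cohorts would therefore not be visible.

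Gene names came from the platform's annotation table. They were compared through gene IDs with a RefSeq gene table of GRCm38.p6, used for names only, which held the gene IDs of 21698 of the probe sets with 1 symbol and changed 0 symbols. Of the 35556 probe sets, 21789 have 1 gene symbol, 1621 have several and 12146 have none in that table. No gene was named from a probe set with several. The 6612 probe sets with the lowest numbers, none of which has a symbol, were taken to be the array's control block and left out, which left 28944. A gene with several probe sets (999 of 19938 genes) was represented by the one with the highest mean. Only 5 of the list memberships had probe sets on both sides of the background limit.

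Before the data were examined, 27 gene lists, the background rule, the tests, their alternatives and the rule for naming genes were fixed. Of 523 list entries, 477 matched a gene with a probe set of its own, and the other 46 were not analysed here. The background limit of each array was the 95th percentile of 106 probe sets of 104 genes specific to other organs. Values above it are called above background. The rule lets about 5% of such genes through by construction. The naming rule allowed a fixed set of genes tied to the project and stage, the first 4 measured members of each list, members on the minority side of that limit where these were 5 or fewer, and at most 20 named probe sets past the variance test, taken by SD. Genes named outside the rule are said to be chosen after their values were seen, except those named as the members that passed a test.

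The position of a list was its median over genes of the 3-array mean, set against 10000 random lists of the same size (two-sided permutation test). The shift of a list was the SD over arrays of its mean deviation from the 3-array mean, set against 10000 random lists matched on level in 20 bins (one-sided permutation test). Both were adjusted by Benjamini-Hochberg over 25 lists, leaving out the sex-linked and background lists. The smallest p that these permutations can give is 0.0002 two-sided and 0.0001 one-sided. Random lists treat genes as independent, so a list of co-regulated genes passes more easily. Variable probe sets were found with limma 3.58.1 in R 4.3.3. An intercept-only fit gave each probe set's variance, and an F test compared it with a robust mean-dependent prior. Other steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. No test between conditions exists with 1 group, and a single array's departure has no replicate of its own.

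Each procedure was tested on simulated data. Among 28944 simulated probe sets, the variance test recovered 0% of shifts of 1 log2 unit on 1 array, 44% of shifts of 2 and 100% of shifts of 4 or 6, with 9 false calls, and it called 0 probe sets when nothing was shifted, where 5.24% had an unadjusted p under 0.05. The shifts, 50 of each size, were planted together, and many large shifts ease the Benjamini-Hochberg limit. With the 6 calls of the real data, recovery of shifts of 2 is likely lower. In simulations on 19938 genes, the shift test at an unadjusted p under 0.05 found 22% of lists of 18 genes that moved by 0.05 on 1 array, 80% of those that moved by 0.1 and 2.5% of unmoved lists. Every simulated gene had independent noise of the same SD, the median of the real genes. Real genes differ in spread, so these rates need not hold for the real arrays, where power may be lower. The position test found 18% of lists raised by 0.5 log2 units, 32% of those raised by 1, 84% of those raised by 2 and 4.5% of unraised lists. It therefore has little power for a list about 1 log2 unit above random lists, such as the ETS family. The number of arrays limits the precision of every SD.

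Alternatives were quantile normalization, median centring, leaving out each array in turn, other background limits, other ways to represent a gene or a list, other random lists and other variance priors. A variant without cross-hybridising probe sets did not apply, since the array's numeric IDs mark none, nor did a floor for linear values.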

Results

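Gene expression was measured by microarray in 3 samples of CD4+ CD8+ double-positive (DP) thymocytes, the stage at which developing T cells carry both coreceptors and rearrange the T cell receptor alpha locus. Each sample came from a cohort of littermate wild-type C57BL/6 mice aged 5 to 6 weeks and was sorted on beads for CD8 and then CD4. The arrays belong to a project that mapped Ets1, Runx1, RNA polymerase II and histone marks in thymocytes of Rag2-deficient mice and the E protein E47 in DP cells, and they record which genes DP cells express. The labels name no second condition, so the comparisons were between gene groups within these cells and between the 3 cohorts. Each array gave 35556 log2 values with no missing entries, with lower and upper quartiles of 5.39 and 8.64 on array 1 and of 5.41 and 8.62 on arrays 2 and 3. The number of arrays limits the precision. A probe set was called above background where it exceeded the 95th percentile of genes specific to other organs, which was 7.20, 7.25 and 7.22 on arrays 1, 2 and 3. By this rule 8636 of 19938 genes (43.3%) lay above background on all 3 arrays. A probe set's signal also depends on the affinity of its probes, so levels were compared between lists of genes and not between single genes.

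The genes that define the DP stage and the T cell receptor machinery were expressed at high values in all 3 cohorts. All 17 measured DP stage genes lay above background on every array. The recombination activating genes Rag1 and Rag2, whose products rearrange the antigen receptor loci, had values of 13.51 ± 0.10 and 9.25 ± 0.48 (log2, mean ± SD, n = 3 here and below). The sort markers Cd4, Cd8a and Cd8b1 had 11.74 ± 0.15, 13.19 ± 0.14 and 11.96 ± 0.18. Dntt, the terminal transferase that adds untemplated bases at receptor joints, had 12.73 ± 0.23, and Ptcra, the pre-T cell receptor alpha chain, had 8.34 ± 0.11. All 19 measured genes of the T cell receptor complex and its proximal signalling lay above background, among them Cd3e at 12.08 ± 0.19, Cd3d at 11.50 ± 0.07, Cd3g at 12.83 ± 0.14 and Cd247 at 10.41 ± 0.05. Of 18 T-lineage transcription factors, 17 lay above background on all arrays, including Lef1 at 11.39 ± 0.15, Bcl11b at 11.63 ± 0.04, Gata3 at 10.44 ± 0.05 and Notch1 at 10.66 ± 0.18. The exception was Rora, a nuclear receptor, which exceeded background on array 1 alone, with 7.37, 6.76 and 6.69 on arrays 1, 2 and 3. The list medians were 11.58 ± 0.12 for DP stage genes, 11.09 ± 0.07 for the receptor list and 10.44 ± 0.04 for the transcription factors, against 6.85 for all genes. Each lay above all 10000 random lists of the same size (permutation test across genes, Benjamini-Hochberg adjusted p = 0.00056 over 25 lists, which rests on the smallest p that the permutations can give). Genes are not independent replicates, so these p-values describe the lists in these cells. The random lists were drawn from all genes, of which 43.3% lay above background on all 3 arrays. Here and below, passing this test of position therefore shows little beyond detection.

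**Figure D1:**
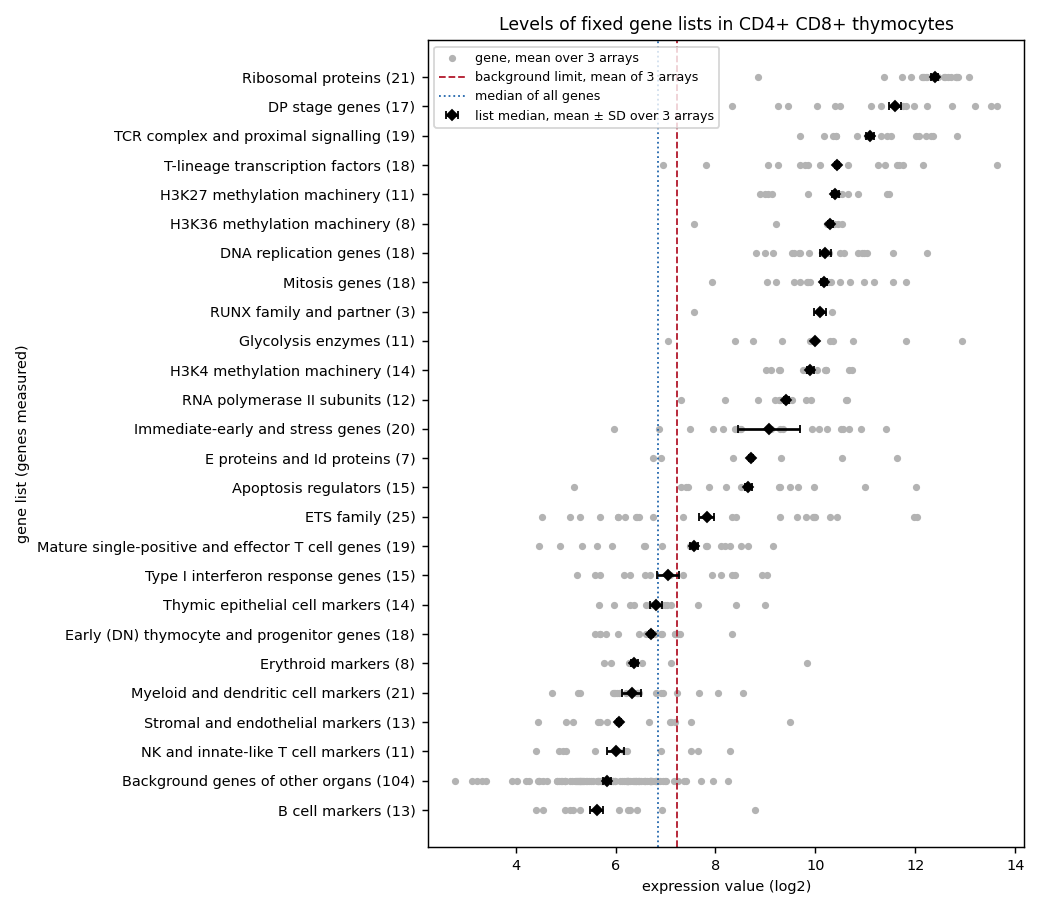
Each row is a gene list, with the number of its measured genes; the x axis is the log2 expression value, grey points are genes and black diamonds are the list median (mean ± SD over 3 arrays). DP stage genes and ribosomal proteins have medians of 11.58 and 12.38, while B cell markers have a median of 5.62, below the background limit.

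The genes of the transcription factors that the project mapped by chromatin immunoprecipitation were all expressed. Ets1 had a value of 12.02 ± 0.05, Runx1 of 10.09 ± 0.12, and Tcf3, the gene that encodes E47 and its splice variant E12, of 10.53 ± 0.13, a value for the gene that does not separate the 2 products. Among 25 measured ETS family genes, 14 lay above background on all arrays and 11 on none. Ets2 at 11.98 ± 0.02 and Fli1 at 10.30 ± 0.02 were among the 14, whereas Spi1, which encodes the myeloid regulator PU.1, had 5.69 ± 0.15 and lay below background on every array. The ETS list as a whole, with a median of 7.82 ± 0.15, did not pass the threshold against random lists (permutation test, adjusted p = 0.31). Runx3, with 7.57 ± 0.06, and Cbfb, the shared partner of RUNX proteins, with 10.33 ± 0.08, both lay above background. Runx3 was near the limit, with 7.62, 7.50 and 7.60 on arrays 1, 2 and 3. It lay below the 99th percentile of the background genes there, which was 8.017, 7.911 and 7.905. The 3 measured RUNX and partner genes had a median above 98.3% of random lists, which did not pass the threshold (permutation test, adjusted p = 0.067). Of the E proteins and their Id antagonists, Tcf12 (11.63 ± 0.07), Id3 (9.31 ± 0.08), Id2 (8.34 ± 0.34) and Tcf4 (8.69 ± 0.06) joined Tcf3 above background. Id1, with 6.92 ± 0.17, and Id4 did not exceed background on any array, and the list of 7 did not pass the threshold (permutation test, adjusted p = 0.26).

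The genes of the machinery that writes and removes the histone marks of the project were expressed throughout. All 14 genes of the H3K4 methylation list, all 11 of the H3K27 list and all 8 of the H3K36 list lay above background on every array. Kmt2a, an H3K4 methyltransferase, had 10.22 ± 0.04, Kmt2d had 10.04 ± 0.14, Ash2l had 9.76 ± 0.13 and Wdr5 had 9.11 ± 0.13. Among Polycomb genes, Ezh2, the main H3K27 methyltransferase, had 11.47 ± 0.04, Ezh1 had 8.99 ± 0.22, Suz12 had 10.86 ± 0.10 and Eed had 9.05 ± 0.12, although not every Eed probe set exceeded background. Setd2, which trimethylates H3K36, had 10.37 ± 0.13 and Nsd1 had 10.46 ± 0.07. All 12 RNA polymerase II subunits lay above background, with 10.63 ± 0.13 for Polr2a, the largest subunit. The 3 histone lists exceeded random lists at an adjusted permutation p of 0.00056, and the polymerase subunits at 0.011. As the random lists were drawn from all genes, detected or not, this adds little to the detection of these lists.

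Proliferation and growth genes were also high. All 18 measured DNA replication genes and all 18 mitosis genes lay above background, with list medians of 10.20 ± 0.11 and 10.18 ± 0.06 (permutation test, adjusted p = 0.00056 for each). Pcna, the replication clamp, had 12.23 ± 0.22, Mcm2, a helicase subunit, had 10.85 ± 0.05, Mki67 had 11.55 ± 0.07, and Top2a, a topoisomerase with a further probe set below background, had 11.81 ± 0.07. All 21 measured ribosomal protein genes lay above background, with a median of 12.38 ± 0.07 (permutation test, adjusted p = 0.00056). Of 11 glycolysis enzymes, 10 lay above background (permutation test, adjusted p = 0.0023), with Hk1 at 12.93 ± 0.10 and Ldha at 11.81 ± 0.06. Hk2 exceeded background on array 1 alone. Of 15 apoptosis regulators, 12 lay above background, and the list did not pass the threshold (permutation test, adjusted p = 0.095). Its survival genes Bcl2 and Mcl1 had 8.52 ± 0.19 and 12.01 ± 0.14, and Bcl2l1 lay above background too. Bbc3 and Pmaip1 exceeded background on some arrays, and Fasl, the death ligand, did not on any (5.16 ± 0.06). Of 15 type I interferon response genes, 7 lay above background, Irf7 among them (8.38 ± 0.12), and Ifit1 (6.17 ± 0.28) was not (permutation test, adjusted p = 0.86). That count was 4 with the 99th percentile of the background genes as the limit.

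Genes of earlier and later T cell stages were less uniformly detected. Of 18 early thymocyte and progenitor genes, only Dtx1, a Notch target, lay above background on all arrays (8.34 ± 0.00). Kit, the stem cell factor receptor, had 6.78 ± 0.09 and Il2ra, the CD25 chain, had 6.60 ± 0.35, both below background on every array. Without array 1, a setting chosen after the data were seen, 2 genes of this list were above background on the remaining arrays, against 1 with all arrays, and 4 were above a limit of the background median plus 1 log2 unit. Of 19 mature single-positive and effector genes, 10 lay above background on all arrays, including Ccr7 (8.19 ± 0.14), S1pr1 (7.83 ± 0.24) and Klf2 (8.66 ± 0.41), which direct or mark thymic exit. With the 99th percentile as the limit, 6 did. Il7r, the interleukin 7 receptor, exceeded background on 2 arrays, with 8.02, 7.16 and 7.36 on arrays 1, 2 and 3. Neither list passed the threshold against random lists (permutation test, adjusted p = 0.88 for the early list and 0.53 for the mature list).

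Markers of other cell types that a thymus sort could hold were mostly at background. Of 13 B cell markers, only Cd79b lay above background on all arrays (8.78 ± 0.05), while Cd79a had 5.09 ± 0.15 and Ms4a1, which encodes CD20, had 4.54 ± 0.26. Of 21 myeloid and dendritic markers, the class II genes Cd74 (8.05 ± 0.78) and H2-Ab1 (8.56 ± 0.68) lay above background on all arrays. Csf1r, Itgam, Itgax and Lyz2 did not exceed background on any array, with 6.43 ± 0.16, 6.81 ± 0.18, 5.98 ± 0.28 and 6.47 ± 0.23. Of 14 thymic epithelial markers, Cldn4, Ly75 and Ccl25 exceeded background on all arrays, the last by only some of its probe sets. Krt8 and Krt18, the latter chosen after its values were seen, did so on array 3 alone, with 7.55 and 7.58 there, while Foxn1 (6.38 ± 0.08) and Psmb11 (6.79 ± 0.21) did not. Of 8 erythroid markers, only Tfrc, the transferrin receptor, lay above background (9.83 ± 0.12). Of 13 stromal and endothelial markers, Pecam1 (9.49 ± 0.04) and Col1a1 (7.50 ± 0.03) did, and of 11 markers of NK and innate-like T cells, Sox13, Gzma and Prf1 did. None of these 6 lists passed the threshold against random lists (permutation test, adjusted p from 0.1 for B cells to 0.99 for epithelium). These small counts depended on the limit. With the 99th percentile, the myeloid count was 0, the stromal count 1 and the NK count 1, and with the median plus 1 log2 unit the epithelial count was 5, the erythroid 2 and the stromal 5. Without array 2, a setting chosen after the data were seen, the myeloid count was 4. As a measure of the rule itself, 5 of 104 genes of other organs lay above background on all arrays, namely Acta1, Tnnt3, Mbp, Sox1 and Nkx2-5, against 2 with the 99th percentile and 10 with the median plus 1.

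The 3 cohorts gave closely similar profiles, with array 1 farther from the other two. Pearson's r across 28944 probe sets was 0.996 between arrays 2 and 3, 0.993 between arrays 1 and 2, and 0.993 between arrays 1 and 3. The values of 31 probe sets differed by more than 1 log2 unit between arrays 2 and 3, against 139 between arrays 1 and 2 and 123 between arrays 1 and 3. The median SD over the 3 arrays was 0.115. At this number of arrays, 6 probe sets varied by more than probe sets of the same level (limma variance test against a mean-dependent robust prior, Benjamini-Hochberg adjusted p under 0.05). An unadjusted p under 0.05 was found for 1350, or 4.66% of those tested, and for 5.24% in the simulation with nothing shifted. The prior was fitted to the variances under test, and the simulation drew from that prior. Neither share therefore measures how much the cohorts differ. Of the 6, 4 belonged to sex-linked genes and 2 have no gene symbol here. Xist, the RNA that silences an X chromosome in females, had 11.65, 5.40 and 5.68 on arrays 1, 2 and 3 (adjusted p = 0.00869). The Y-linked genes Eif2s3y, Kdm5d and Uty had 4.21, 10.29 and 10.08, 4.46, 9.10 and 8.97, and 4.00, 8.96 and 8.98 (adjusted p = 0.00869, 0.0208 and 0.0189). The unnamed probe set 10608138 had a like pattern, with 4.89, 10.46 and 10.55 (adjusted p = 0.00869), and the other unnamed one, 10485357, was high on array 3 alone. With dim arrays set at the background limit, Xist was at least 21.1-fold higher on array 1 than on either other array. Eif2s3y was likewise at least 7.37-fold lower on array 1, Kdm5d at least 3.42-fold and Uty at least 3.39-fold lower. Without array 1 the SD of Xist was 0.198 and 18 probe sets were called, none of them these 4 genes. Without array 2 or array 3 the SD of Xist was 4.22 and 4.42, against 3.53 with all arrays, and that of Eif2s3y was 4.15 and 4.30, against 3.45. The limma test on the 2 remaining arrays called 0 in both cases, with 1120 and 1010 at an unadjusted p under 0.05. A prior that was not robust gave 3 calls, without Kdm5d, Uty and probe set 10485357, and a robust prior without a trend gave 0, with 1157 at an unadjusted p under 0.05.

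**Figure D2:**
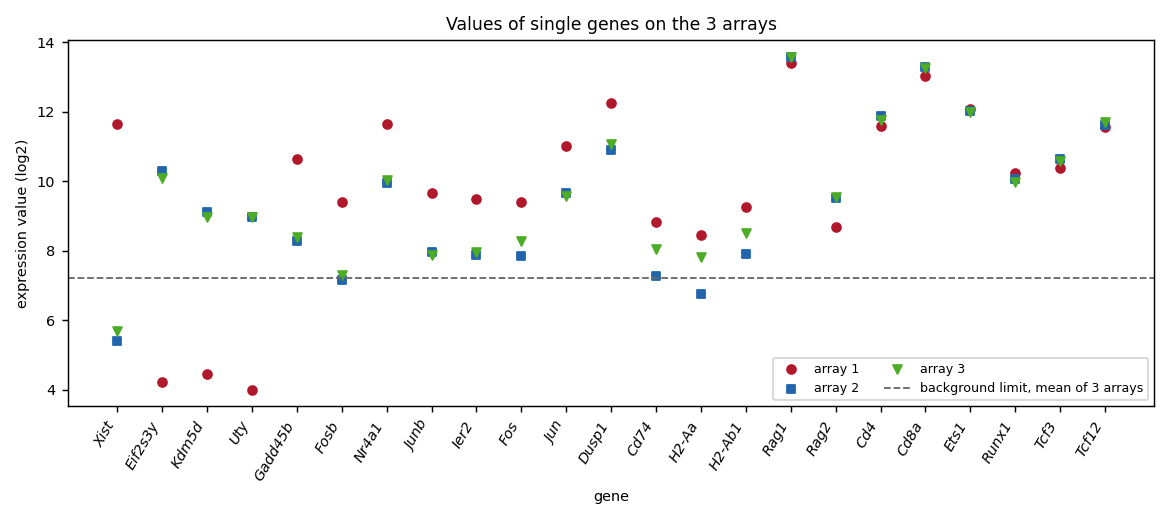
Each column is a gene, the y axis is the log2 expression value, and the points are the values on arrays 1, 2 and 3, with the background limit dashed. Xist lies at 11.65 on array 1 and at 5.40 and 5.68 on arrays 2 and 3, the Y-linked genes show the reverse, and Ets1 lies between 11.98 and 12.07.

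Whole gene groups also shifted between cohorts, most of all, among the 25 lists, the immediate-early and stress genes. These are transcribed within minutes of a stimulus. Their 20 measured members deviated on average by 0.59, -0.31 and -0.28 from the mean of the 3 arrays on arrays 1, 2 and 3. The SD of the list shift was 0.51, against a median of 0.025 for random lists of the same levels (permutation test, adjusted p = 0.0025), and 18 of 20 members were highest on array 1. Over all genes, 34.5% were highest and 39.3% lowest on array 1. No member passed the variance test over all probe sets and 12 did when adjusted over the list alone. Fos, the first listed, had 9.39, 7.86 and 8.27 on arrays 1, 2 and 3, Jun had 11.01, 9.65 and 9.56 and Egr1 had 8.55, 8.28 and 8.33, of which Fos and Jun were among the 12. Fosb, below background on array 2, had 9.40, 7.17 and 7.30 and was also among the 12. Gadd45b, Nr4a1 and Junb, chosen after their values were seen, were 5.17-fold, 3.25-fold and 3.20-fold higher on array 1 than on array 2. Without array 1 the SD of the list shift was 0.019 and the call was lost (permutation test, adjusted p = 0.56).

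A further 8 lists, making 9 of 25, shifted by more than random lists of the same levels. DP stage genes deviated by -0.12, 0.07 and 0.05 on arrays 1, 2 and 3, with 15 of 17 members lowest on array 1 (permutation test, adjusted p = 0.013). Rag2 had 8.69, 9.51 and 9.54 on arrays 1, 2 and 3, and Dntt had 12.47, 12.86 and 12.87, neither past the variance test. Myeloid and dendritic markers shifted by 0.22, -0.18 and -0.04 on arrays 1, 2 and 3 (permutation test, adjusted p = 0.0037). Their class II genes Cd74 (8.83, 7.27 and 8.05), H2-Ab1 (9.26, 7.91 and 8.50) and H2-Aa (8.44 on array 1 and 7.81 on array 3, and below background on array 2) were the 3 members that passed the variance test adjusted over the list alone. NK and innate-like markers shifted by 0.18, -0.14 and -0.04, and mature T cell genes by 0.17, -0.14 and -0.02 (permutation test, adjusted p = 0.019 and 0.027). DNA replication genes deviated by 0.13, -0.09 and -0.04, with 16 of 18 members highest on array 1 (permutation test, adjusted p = 0.0069), whereas mitosis genes did not pass the threshold (adjusted p = 0.24). Ribosomal proteins (0.11 on array 1 and -0.10 on array 2), interferon response genes (-0.10, 0.12 and -0.02) and thymic epithelial markers (-0.10, 0.06 and 0.05) passed at adjusted permutation p of 0.0067, 0.037 and 0.048. Of the myeloid, NK and epithelial lists, 2 of 21, 3 of 11 and 3 of 14 members lay above background on all arrays, so their shifts include values at background. The directions held under quantile normalization and median centring, except that the ribosomal deviation on array 3, -0.003, was 0.005 under the former. The ribosomal call was lost after quantile normalization (permutation test, adjusted p = 0.27), the interferon call after median centring (adjusted p = 0.051), and the epithelial call after either or without any single array.

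Several of these calls rested on array 1. Without it the calls ended for DP stage genes (SD of the shift 0.018 against 0.108), NK markers (0.071 against 0.167), epithelial markers (0.009 against 0.090) and DNA replication genes (0.038 against 0.112). The SD fell to 0.096 from 0.199 for myeloid markers and to 0.084 from 0.157 for mature T cell genes, both still past the threshold. Without array 2 the calls ended for interferon genes (0.055), ribosomal proteins (0.077) and epithelial markers (0.105), and without array 3 for epithelial markers (0.114). The receptor signalling, T-lineage factor, ETS, RUNX and E protein lists did not pass the threshold with all arrays (permutation test, adjusted p from 0.14 to 0.89). Without array 1 the ETS list (0.07, adjusted p = 0.017) and the mitosis list (0.062, adjusted p = 0.011) did. The receptor signalling list passed under quantile normalization (adjusted p = 0.042).

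**Figure D3:**
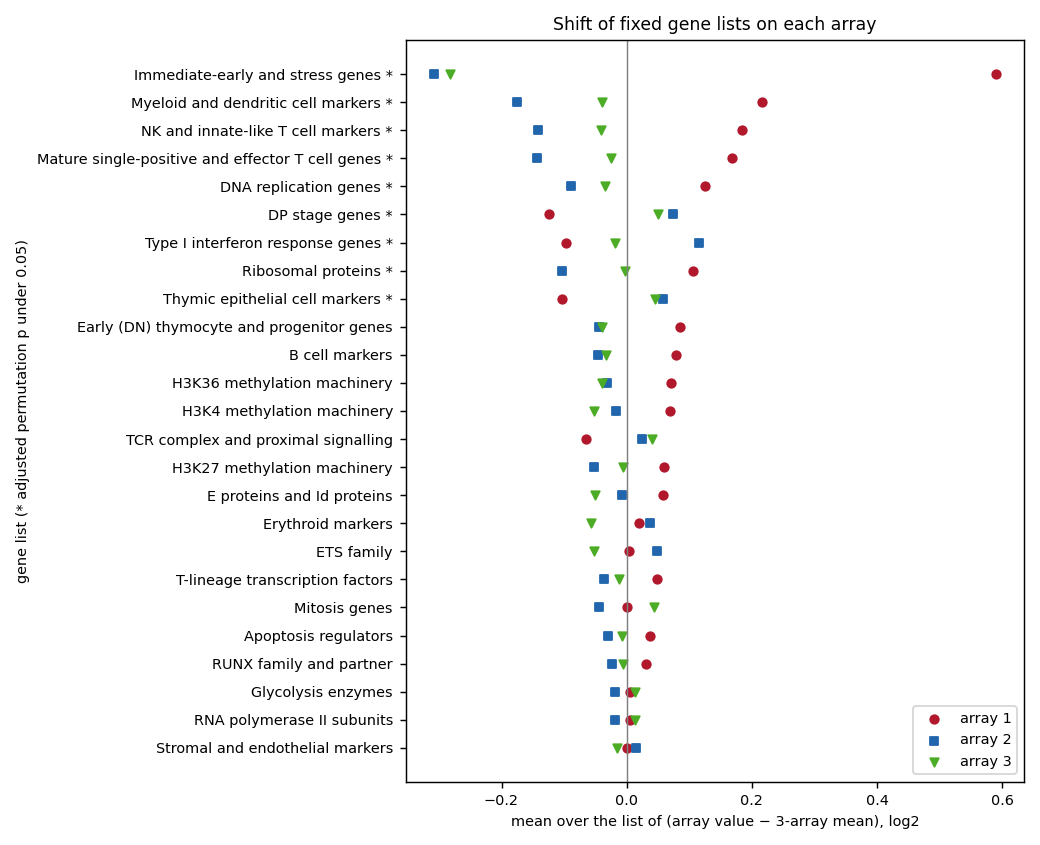
Each row is a gene list and the x axis is the mean over its genes of the array value minus the 3-array mean (log2), with a point for each of arrays 1, 2 and 3; stars mark an adjusted permutation p under 0.05. Immediate-early genes lie at 0.59 on array 1, farther from 0 than any other of the 25 lists.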

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

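No paired analysis was possible because the series holds 1 group. The tests over all probe sets of the file and over those with 1 symbol (4 calls), and list counts without each array, were chosen after seeing the data. Positions of lists against random lists kept their side of the threshold under all alternatives run, in 12 lists above random lists and 0 below, and the counts of probe sets and genes above background stayed within 1.5 times (9377 to 13157 probe sets and 6929 to 9626 genes). Counts of list members above background moved by over 1.5 times in 14 of 189 cases. Over probe sets above background alone the lowest Pearson r was lower, 0.984, and so was the median SD, 0.0961. Over leave-one-out fits the lowest r ran from 0.993 to 0.996 and the median SD from 0.0707 to 0.106, the lower SD without array 1. The number of variable probe sets was the least stable result. It ran from 0 to 18 over leave-one-out fits, which have 1 array fewer to estimate each variance, and was 3 with a prior that was not robust, 0 with a robust prior without a trend, 0 when only probe sets above background were tested and 0 over all probe sets of the file. The filter on background removes genes silent on any array, Xist and the Y-linked genes among them. Adding the control block raised the spread of variances (prior degrees of freedom 2.85 against 4.71), and the causes of the remaining differences were not tested.

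For list shifts, values are the SD of the shift in log2. Under quantile normalization the receptor signalling list gained a call (0.085), and the epithelial (0.084) and ribosomal (0.055) lists lost theirs. Under median centring the epithelial (0.081) and interferon (0.098) lists lost theirs. The epithelial list also lost its call with the median over probe sets of a gene (0.084) and with random lists not matched on level (0.09). With the median over a list's genes the receptor signalling (0.081) and H3K4 (0.099) lists gained calls. The cause was not tested. Over leave-one-out fits the SD ran from 0.018 to 0.14 for DP stage genes, 0.031 to 0.07 for the ETS family, 0.009 to 0.114 for epithelial, 0.071 to 0.23 for NK, 0.038 to 0.152 for replication, 0.03 to 0.062 for mitosis, 0.019 to 0.635 for immediate-early, 0.055 to 0.15 for interferon and 0.072 to 0.148 for ribosomal genes. Of these, the ETS and mitosis lists gained calls without array 1 (0.07 and 0.062).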

Other observations

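The gene families and single genes in this paragraph, the families defined by symbol and apart from the class II list, were chosen after seeing the data, and their p-values are adjusted over 14 added lists. Of 39 proteasome subunit genes, 37 lay above background on all 3 arrays, and of 77 mitochondrial ribosomal protein genes 74 did (permutation test of position, adjusted p = 0.0007 for each). Of 1027 olfactory receptor genes, 5 did, and the family lay below all random lists. It also passed the shift test, by 0.011, 0.013 and -0.024 on arrays 1, 2 and 3 (permutation test, adjusted p = 0.039). As 1019 of its genes lay above background on no array, a list almost entirely at background can pass that test. Among 51 small nucleolar RNAs, which guide modification of ribosomal RNA, 45 lay above background and 38 were highest on array 1, with list shifts of 0.24, -0.14 and -0.10 on arrays 1, 2 and 3 (permutation test, adjusted p = 0.00047). Over all genes, 34.5% were highest on array 1. Of 12 immunoglobulin genes 8 were highest on array 1, and the list passed the shift test (permutation test, adjusted p = 0.00047), but 10 lay above background on no array and the other two, Ighm and Jchain, on array 1 alone. The size of that shift is therefore not interpretable. A further 5 class II genes, a list written before its values were seen and with 2 members above background on all arrays, shifted by 0.25, -0.17 and -0.09 (permutation test, adjusted p = 0.016), with H2-Eb1 at 8.82, 7.77 and 8.40. Zinc finger genes named Zfp, 347 in number, shifted by -0.043, 0.028 and 0.015 (permutation test, adjusted p = 0.0014). The 2 T cell receptor gamma and delta genes with a probe set of their own passed the same test (adjusted p = 0.0073), but this rests mainly on Trgv1, below background on every array, and Trdv2-2 had 8.41, 7.95 and 8.18. The 7 alpha and beta genes did not pass the threshold (permutation test, adjusted p = 0.23). The 8 Gimap genes, GTPases of lymphocytes, shifted by -0.09, -0.05 and 0.14 (permutation test, adjusted p = 0.036). Hes1, a Notch target and the one early thymocyte gene past the variance test adjusted over its list alone, had 8.11, 6.66 and 6.03. The probe set 10485357, which has no gene symbol here, had 6.53, 6.51 and 10.53 on arrays 1, 2 and 3 (limma variance test, adjusted p = 0.0281), so array 3 differed from both others. Its SD was 2.32 with all arrays, 0.014 without array 3 and 2.83 without array 2, where it was still not called (adjusted p = 0.198). With all arrays it also lost its call under a prior that was not robust (limma variance test, adjusted p = 0.0731). The same held for a robust prior without a trend (adjusted p = 0.28).

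In the 3 patterns below, the tests of mixed-sex cohorts, scaling, class II-bearing cells, B-lineage cells and the share of DP cells were chosen after the results were seen. Those on escape genes, further immediate-early genes and further myeloid genes were written before those genes were looked at. The labels put the arrays in 1 group, so no biological explanation from the design was tested. Single genes of the further lists named as examples were chosen after their values were seen.

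The first pattern is the split of sex-linked genes, with Xist high on array 1 and the Y-linked genes high on arrays 2 and 3. Like shares of both sexes on any of the arrays are argued against, since on each array Xist or every measured Y-linked gene lay at least 1.78 log2 units below its own value on another array, with dim values set at the background limit, although a small share of the other sex is not excluded. Mainly male material on array 1 is argued against, since every measured Y-linked gene lay below background there. Mainly female material on arrays 2 and 3 is argued against too, since Xist lay below background on both. The explanation left is that array 1 came mainly from females and arrays 2 and 3 mainly from males, which the labels do not state. As a test, the X-linked genes Eif2s3x and Ddx3x, known to escape X inactivation in mice, were both highest on array 1, with 11.20, 10.69 and 10.63 and 12.01, 11.98 and 11.98 on arrays 1, 2 and 3, but the pair did not pass the test against random pairs of the same level (permutation test, p = 0.073). With Ddx3x nearly level, the pair does not decide, and the explanation rests on Xist and the Y-linked genes. Xist was above background on array 1 alone, and each measured Y-linked gene on arrays 2 and 3 alone. Because that split coincides with array 1, sex cannot be separated from anything else that sets array 1 apart.

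The second pattern is the rise of immediate-early genes on array 1. Scaling that depends on intensity alone is argued against, since the SD of the list shift was 0.51, against a median of 0.025 for random lists matched on level. Quantile normalization left the list's deviation on array 1 at 0.58 (95% bootstrap interval over genes 0.374 to 0.795), from 0.59 before. It changed the ribosomal deviation there from 0.106 to 0.053. The sorted values of any 2 arrays already differed by at most 0.15. Quantile normalization could therefore hardly have brought 0.59 to 0, and it does not decide. A further 16 immediate-early genes, written down first, also moved and were highest on array 1, in 13 of 16 cases (permutation test, p = 0.0001, the smallest the permutations can give), with Nfkbia at 12.51, 11.44 and 11.41, whereas Socs3, Sgk1 and Ccn1 were not highest there. RNA from class II-bearing cells stays open. Array 3 lay 0.029 of the way from array 2 to array 1 for the immediate-early list and 0.528 for Cd74, H2-Aa and H2-Ab1. That is a difference of -0.499 (95% bootstrap interval over genes -0.62 to -0.382). For the 5 further class II genes array 3 lay at 0.182, a difference of -0.152 (-0.521 to 2.002). These intervals resample genes, only 3 in the first class II set, and carry no error between arrays. Of the 5 further genes, 2 lay above background on all arrays, and H2-Aa was below background on array 2. The positions therefore do not decide. Handling, stimulation in the animal and sex also remain open and were not tested, because each may differ between array 1 and the others and no sample separates them.

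The third pattern is the higher level of class II and myeloid genes on array 1. More myeloid and dendritic cells is a candidate explanation: 15 further genes of these cells, written down first, moved with array 1 highest and array 2 lowest, by 0.11, -0.15 and 0.03 on arrays 1, 2 and 3 (permutation test, p = 0.0064). Of the 15, 9 were highest on array 1, against 34.5% of all genes. Of the 15, 5 lay above background on all arrays, of which Cst3, with 10.24, 10.35 and 10.55, and Ctss, with 8.46 on array 1 and 8.71 on array 3, were highest on array 3, and of the 18 members of the myeloid list other than class II genes 0 lay above background on all arrays. B-lineage cells, which also carry class II, stay open too: the fixed B cell markers deviated by 0.079 on array 1, their highest, and did not pass the shift test (permutation test, p = 0.12), with 1 of 13 above background on all arrays, and the immunoglobulin genes, which passed it with array 1 highest, were chosen after seeing the data and lay almost entirely at background, so neither list decides. A lower share of DP cells on array 1 stays open. DP stage genes lay at -0.12 there, with 15 of 17 members lowest. Of 8 lists of other cell types and of early and mature T cell stages, 7 had a positive deviation there. However, that of stromal markers was 0.0005 and that of erythroid markers 0.02, and epithelial markers lay at -0.10. Only the mature T cell list, 1 of the 8, had most of its genes above background. How many myeloid and B cells the bead sort left in each sample was not measured here.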
